A study of Homo sapiens with 36 samples.

How the data were processed

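BEAS-2B cells, an immortalised line of human bronchial epithelium, were measured on 36 Affymetrix GeneChip expression arrays with 54613 probe sets. Per the labels, cells received cigarette smoke condensate (CSC) at 20 µg per ml 2 times a week, the solvent dimethyl sulfoxide (DMSO) alone, or nothing. RNA was taken after each of 4 months, with 3 arrays for each of the 12 groups, per the sample labels and the series design. The labels' extraction protocol instead speaks of a single month of treatment, and their growth protocol also describes lung cancer lines, which were not analysed here. The months are used as the sample labels give them. Per the labels, each array also carries 1 of 8 batch codes, whose meaning is not given in the sources used here. Nothing in the labels says that the 3 replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

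The deposited values are GCRMA expression values, per the submitters' processing notes. GCRMA corrects background by probe sequence, normalizes by quantiles and summarises probe sets. Its version is not given in the sources used here, and no detection calls were used. The log base of the deposited values is not stated. They were read as natural log, because the highest deposited value, 10.67, corresponds to 43045 intensity units in base e and to 1629 in base 2, against a 16-bit scanner limit of 65535. They were divided by the natural log of 2, and every log2 value here rests on that inference. If the deposited values were log2 already, each log2 change would be 0.693 times the one printed. The planned design assumed log2 values, and the same limma test was kept.

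Of the probe sets, 41091 name 1 gene in the platform annotation, 1801 name several and 11721 name none. Symbols were updated through Entrez identifiers for 41037 of them. A gene was represented by the probe set with the highest mean among those naming it alone. For named genes called over the months, every other probe set with a change of opposite sign had a mean under 4 log2. The 59 probe sets of XIST and the Y chromosome were left out of all steps. Of 19740 genes represented, 10673 had a log2 value above 4 on at least 3 arrays and were tested. Values near 2 to 3 lie at the background of GCRMA, where a fall to it or a rise from it is bounded by the background and its fold is understated. Array medians lay between 1.881 and 2.016 on the deposited scale, and no pair of arrays held identical values. The number of arrays limits the precision.

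All comparisons between treatments used limma (version 3.58.1, R 4.3.3) with 12 groups, batch as a fixed block and 19 residual degrees of freedom, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over the 10673 genes. A gene was called at an adjusted p under 0.05. Months 1 and 4 share no batch, so untreated cells were compared between them with batch as a random block, with an estimated correlation of 0.105. Of 30 gene lists, 26 with at least 5 tested members were tested with camera at a preset correlation of 0.01. Samples, the tests above, lists, alternatives and the naming rule were fixed before the data were examined. That rule named the 12 largest rises and falls among called genes with the same sign in all months, up to 4 members of each list, called or not, 16 genes chosen in advance, the 3 largest called rises and falls per month, the 8 smallest p-values for the difference between months, and the 5 largest called rises and falls in each other comparison. ALDH3A1 and SNAI1, from that advance choice, did not pass the filter.

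Other settings, chosen in advance, changed the batch handling, filter, probe set summary, normalization, variance model, array weights, arrays entered and list test, and left out each array in turn. Settings added after the data were seen left out 4 arrays, read the values as log2, compared CSC with untreated cells by month and used another estimate of the array weights. The F test on list means between months and the differences within batches were also added then. In the 36 fits without single arrays, the fits of every probe set and the weighted fits, the random block's correlation was held at 0.105. In the fit of the 6 untreated arrays alone it could not be estimated, since 1 batch alone held 2 of those arrays, and it was held at the same value. In data simulated for 10673 genes, the mean CSC minus DMSO comparison recovered 56.7% of changes of 0.5, 94% of changes of 1 and 100% of changes of 2 on the log2 scale. For month 1 these shares were 8.96%, 40.3% and 87.9%. The simulation drew independent normal noise with each gene's fitted spread, the same in all groups, for randomly chosen genes. It held no background limit, shared culture or wrong label, so the shares may be too high for the real data. There GREM1 was not called at 2.52 over the months, nor CYP1B1 at 4.64 in month 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.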

Results

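Gene expression was measured in BEAS-2B bronchial epithelial cells exposed to CSC, the condensed particulate matter of cigarette smoke, for up to 4 months. There were 12 arrays each for CSC, DMSO and untreated cells, 3 in each month. Levels are log2 intensities under the natural-log reading of the deposited values, and changes would be 0.693 times those given if the values were log2 already.

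CYP1B1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, served as a check of the labels. In months 1 and 2 it averaged 12.12 ± 0.43 and 12.55 ± 0.55 in CSC arrays and 7.40 ± 0.41 and 8.30 ± 0.73 in DMSO arrays (SD, n = 3 each). In months 3 and 4, CYP1B1 went against the label on 4 arrays. The arrays labelled CSC month 3 replicate 1 and CSC month 4 replicate 1 read 6.38 and 7.93. The arrays labelled DMSO month 3 replicate 1 and untreated month 4 replicate 2 read 13.07 and 13.59. All arrays were kept under their given labels, and every direction below that draws on months 3 and 4 carries this doubt.

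**Figure D1:**
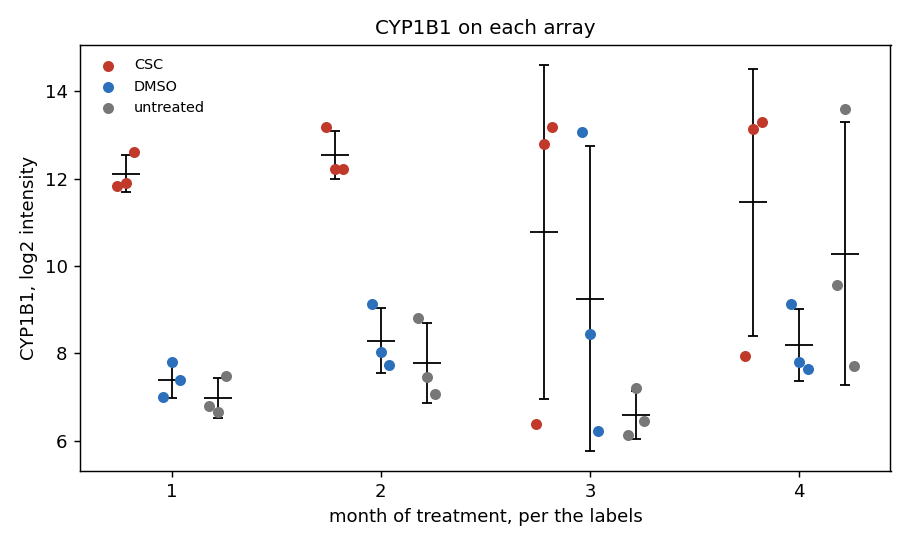
CYP1B1 (log2 intensity) on each of the 36 arrays by month, with treatments in colour as labelled; black bars show the mean and SD of the 3 arrays of a group. In months 1 and 2 the CSC arrays lie apart from both controls, while in months 3 and 4 the arrays at 6.38, 7.93, 13.07 and 13.59 lie on the other side.

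As a mean over the 4 months, cells labelled CSC had higher xenobiotic-response genes and lower epithelial genes than cells labelled DMSO. The epithelial difference lay mainly in months 1 and 2. CYP1B1 was higher by 3.42 ± 0.87 log2 (SE; limma adjusted p = 0.023). IL24, a cytokine gene, was higher by 2.65 ± 0.47 (adjusted p = 0.00218) and SHISA2 by 2.74 ± 0.60 (adjusted p = 0.0102). KRT19, a keratin of simple epithelia, was lower by a log2 change of -3.35 ± 0.85 (adjusted p = 0.0227), and was at -7.28, -4.87, -0.48 and -0.78 in months 1 to 4. CDH1, encoding E-cadherin of adherens junctions, changed by -2.71 ± 0.68 (adjusted p = 0.0222) and CLDN7, a tight junction claudin, by -2.56 ± 0.47 (adjusted p = 0.00286). Among called genes with 1 sign in all 4 months, KYNU, VCAN, PIR, SRPX, PDK4, AHRR, LAPTM5, MAN1A1 and AKR1C1 completed the 12 largest rises, from 2.03 for AKR1C1 to 2.79 for KYNU. SYBU, MAL2, ALPP, FXYD3, SLPI, S100A14, GATA3, L1CAM and STEAP4 completed the 12 largest falls of this kind, from -3.24 for SYBU to -2.42 for STEAP4. The shared sign says little where a month's change was very small, as for SLPI at -0.00481 in month 3 and FXYD3 at -0.0152 in month 4. SYBU stayed lower in those months, at -1.7 and -3.36. In all, 614 of 10673 genes were called, 270 higher and 344 lower. The count was 3247 without the 4 arrays, a set chosen after the data were seen and by CYP1B1 itself. It ranged from 295 without DMSO month 1 replicate 2 to 1571 without CSC month 4 replicate 1, and 15 of these 24 genes, CYP1B1, KRT19 and CDH1 among them, lost their call without some single array.

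Of 7 tested targets of the aryl hydrocarbon receptor, 5 were called higher and none lower (6 higher, adjusted over the list alone), with a mean change of 1.43. AHRR, the receptor's repressor, rose by 2.07 ± 0.40 and TIPARP by 0.95 ± 0.25, and CYP1A1 rose by 1.07 ± 0.31. The list passed camera (adjusted p = 8.92e-05) but not with the correlation estimated from the data (adjusted p = 0.258 with an estimated correlation). Within batches, CYP1B1 differed by 4.06, 4.35, 2.84, 5.58, 4.06 and 5.23 in batches 1, 3, 5, 6, 7 and 8, and by -1.17 in batch 4. Batches 4 and 5 each hold 2 of the 4 arrays. Of 28 targets of NRF2, the regulator of antioxidant genes, 10 were higher and 1, AKR1B10, lower (15 and 1, adjusted over the list alone). AKR1B10 was at -3.68, -0.18, -0.03 and 0.04 in months 1 to 4. NQO1, a quinone reductase, rose by 1.79 ± 0.53, HMOX1 by 1.13 ± 0.29 and the transporter gene ABCC3 by 1.94 ± 0.37. This list also passed camera (adjusted p = 5.09e-07) but not otherwise (adjusted p = 0.336 with an estimated correlation). NQO1, CYP1A1, TIPARP and HMOX1 lost their calls in 26, 23, 11 and 9 of the 36 fits without a single array.

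Of 42 genes of epithelial junctions and keratins, 29 were lower and none higher (35 lower, adjusted over the list alone), with a mean change of -1.31 and adjusted p = 1.47e-26. This call was lost on the second test (adjusted p = 0.0541 with an estimated correlation). OVOL1 and GRHL2, transcription factors of epithelial identity, changed by -0.86 ± 0.08 and -1.79 ± 0.27. These means over the months came from months 1 and 2. In months 1 to 4, OVOL1 was at -2.7, -0.775, 0.08 and -0.06, and GRHL2 at -5.16, -2.23, 0.27 and -0.05. Within batches 1 and 8, both of month 1, the list differed by -3.77 and -2.98, and in month 2 by -2.47 within batch 3 and -0.19 within batch 7. Within batches 4, 5 and 6, of months 3 and 4, it differed by 0.49, -0.20 and -0.33. Of 16 squamous differentiation genes, 9 were lower (10, adjusted over the list alone), including the transglutaminase gene TGM1 at -1.61 ± 0.25 and KLK10 at -2.66 ± 0.49. That list had adjusted p = 1.81e-11, and adjusted p = 0.0541 with an estimated correlation. TGM1, KLK10, OVOL1 and GRHL2 lay near the background in CSC arrays. Their SEs use a spread pooled over all 12 groups, and so may understate the spread of the control arrays in months 1 and 2. TGM1 had an SD of 0.0146 over the CSC arrays and 2.13 over the DMSO arrays, the latter including the change between months. Of 35 mesenchymal genes, 3 were higher, COL6A1, TGFB1 and TWIST2 (6, adjusted over the list alone), and the list had adjusted p = 0.000113, and adjusted p = 0.336 with an estimated correlation. The mesenchymal markers VIM, CDH2 and FN1 were not called over the months, with changes of 0.29, -0.05 and 0.00, and neither were SNAI2, ZEB1, ZEB2 and TWIST1, at 0.16, 0.49, 0.33 and 0.32. ZEB1 gained a call in 9 of the fits without a single array. In month 1 ZEB1, VIM, TWIST1, CDH2 and ZEB2 were at 1.78, 0.905, 0.86, 0.83 and 0.625, and FN1 and SNAI2 at -0.28 and -0.31. Of the 35 mesenchymal genes, 5 were called higher in month 1 and 0 lower.

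Camera also called mitosis genes higher (adjusted p = 0.00507), and genes of endoplasmic reticulum stress (adjusted p = 0.0151), tumour suppressors methylated in lung cancer (adjusted p = 0.0149) and secretory and alveolar cells (adjusted p = 0.0449) lower. With an estimated correlation their adjusted p-values were 0.647, 0.647, 0.106 and 0.336, so none of the 9 called lists held, while 7 lists passed fry, which asks only whether a list moved one way. Single members called were ATF3 in the stress list, TIMP3, SFRP1 and CDH1 among the tumour suppressors, and SLPI and MUC1 in the secretory list, all lower, and none of the 30 mitosis genes. ATF3 lost its call in 26 of the 36 fits without a single array, and the secretory list, with a mean change of -0.81 and a median of -0.17 over 5 members, in 10. Adjusted over the list alone, the stress list had no call, the tumour suppressors kept 3 lower and added RUNX3 as higher, and the secretory list had 2 lower. The other 17 tested lists had adjusted p-values from 0.0565 to 0.973. In the fatty acid synthesis list the mean change was 0.06 and the median -0.07, and for DNA methylation and repair enzymes the mean was -0.02 while camera pointed upward, neither list being called. The lists of ciliated, neuroendocrine, fibroblast, and leukocyte and endothelial markers had too few tested members, and among them UCHL1 was higher by 1.26 ± 0.23 and FAP lower at -0.89 ± 0.13. FAP was at -3.28, -0.29, 0.01 and -0.01 in months 1 to 4 and averaged 2.21 in CSC arrays, at the background, so its SE carries the limit given for TGM1.

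The CSC minus DMSO change of the epithelial genes was largest in month 1, and by month 4 these genes were low in the control arrays too, where the background of the arrays limits the difference that can be seen. CDH1 averaged 10.81 ± 1.65 in DMSO arrays and 5.17 ± 1.92 in CSC arrays in month 1, and 4.00 ± 0.80 and 3.59 ± 0.54 in month 4 (SD, n = 3 each). In month 3, CDH1 averaged 7.23 ± 1.25 in untreated arrays. Replicate 1 of both CSC and DMSO is among the 4 arrays, and CDH1 read 9.40 on CSC replicate 1 and 3.47 and 4.34 on replicates 2 and 3, against 4.87 on DMSO replicate 1 and 7.08 and 7.0 on replicates 2 and 3. The mean change of the epithelial list was -3.41 ± 0.52 in month 1, -1.71 ± 0.48 in month 2, 0.10 ± 0.48 in month 3 and -0.22 ± 0.50 in month 4 (SE), and these differed between months (F test on list means, chosen after the data were seen, adjusted p = 0.00242). The list read 7.19 on DMSO month 1 replicate 1, against 9.46 and 9.22 on replicates 2 and 3. Replicate 1 lies in batch 2, which has no CSC array, so it has little weight in the month 1 change. In month 2, the list mean of replicate 1 was 5.76 in DMSO and 5.75 in untreated cells, both in batch 7, near the CSC arrays, while untreated replicate 2 of that batch read 7.82. Without the 4 arrays the list difference was -0.67 ± 0.59 in month 3 and -0.36 ± 0.62 in month 4. The squamous list went from -3.92 ± 0.43 to 0.04 ± 0.42 (adjusted p = 4.85e-05). The tumour suppressor list went from -1.48 ± 0.29 to -0.11 ± 0.28 (adjusted p = 0.0381), and no other list passed this test. For the aryl hydrocarbon receptor list it gave adjusted p = 0.998. Among called genes, KLK10, KRT13 and KLK5 showed the 3 largest falls of month 1, at -7.67, -7.41 and -7.39, and IL24, VCAN and AHRR the 3 largest rises, at 4.47, 4.44 and 4.06, although VCAN lost this call in 8 of the 36 fits without a single array. KLK10 and KRT13 averaged 2.31 and 2.07 in CSC arrays, at the background. IL24 averaged 3.03 in DMSO arrays, and AHRR read 5.79, 3.38 and 3.38 on DMSO month 1 replicates 1 to 3. The background therefore limits these sizes and their ranks.

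**Figure D2:**
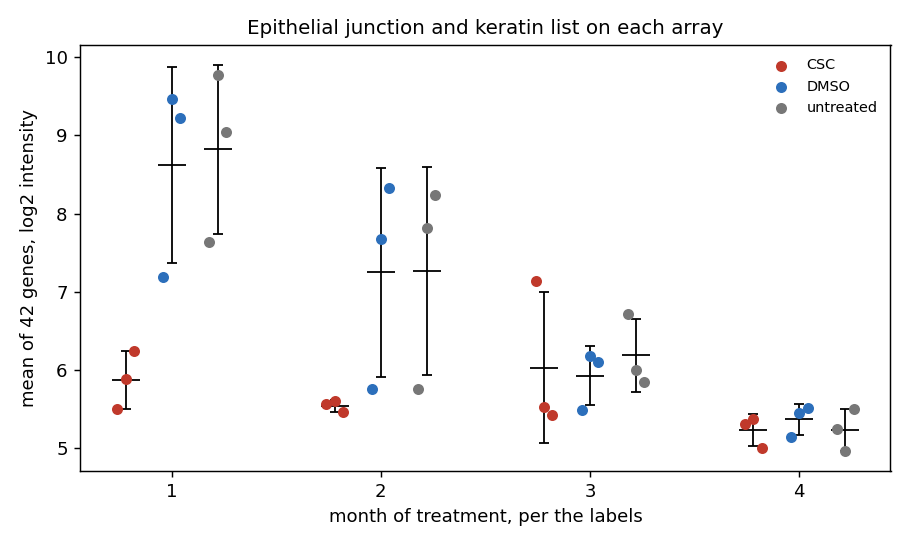
Mean log2 intensity of the 42 tested epithelial junction and keratin genes on each of the 36 arrays by month, with treatments in colour as labelled; black bars show the mean and SD of the 3 arrays of a group. The control arrays come down from month 1 to month 4, to the level of the CSC arrays.

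**Figure D3:**
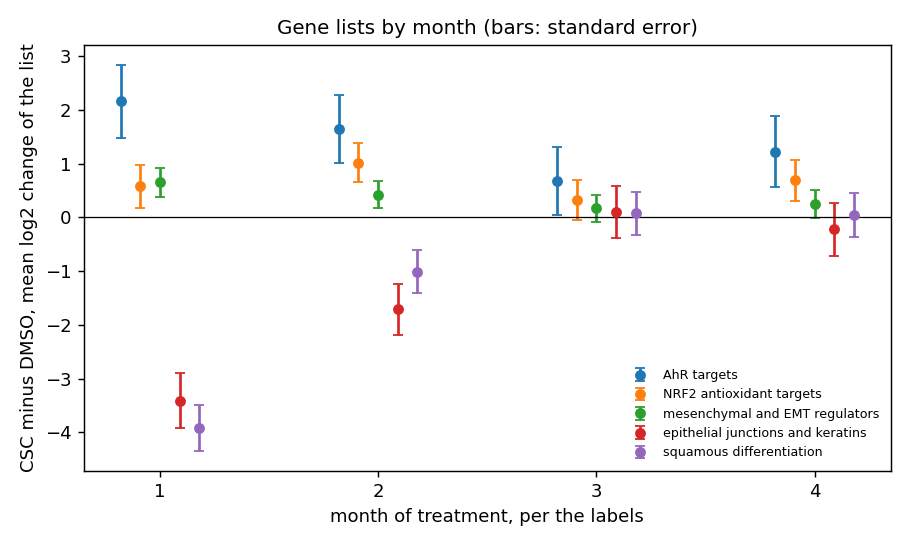
CSC minus DMSO mean log2 change of 5 gene lists in each month, with standard errors of the fit. The epithelial and squamous lists start at -3.41 and -3.92 in month 1 and lie at -0.22 and 0.04 in month 4, and month 3 includes 2, and month 4 1, of the 4 arrays whose CYP1B1 goes against the label.

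In month 1, 513 genes were called, 140 higher and 373 lower. In months 2, 3 and 4 limma called 0 genes, with 805, 110 and 524 at an unadjusted p under 0.05. Without the 4 arrays, those months had 131, 387 and 730 called genes. Each test by month used a spread pooled over all 12 groups, the 4 arrays included. With that spread CYP1B1, at 4.64 and 4.25 in months 1 and 2, was called in neither of them. A count of 0 therefore does not show that a response was absent. For genes near the background in most groups, the pooled spread can instead understate that of month 1. The change differed between months for 164 genes, among them KANK4, GJB5, FAT2 and FGFBP1, at -5.12, -3.23, -4.51 and -6.06 in month 1 and at -0.02, -0.01, -0.03 and -0.01 in month 4. Both counts depended on the batch block, and were 242 for month 1 and 9 for the difference between months without it. Batch 2 holds 0 CSC arrays, 1 DMSO array, month 1 replicate 1, and 1 untreated array. With the block, the month 1 change therefore rests mainly on DMSO replicates 2 and 3. Without DMSO month 1 replicate 1 the counts were 444 and 147. Without DMSO month 1 replicate 2 they were 239 and 87, and without DMSO month 1 replicate 3 they were 305 and 95.

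Against untreated cells, the second control, the cells labelled CSC again had higher CYP1B1 and lower epithelial genes as a mean over the months. Of the 42 epithelial genes tested, 29 were called lower and 0 higher, with a mean change of -1.47, and the lists were not tested for this comparison. CYP1B1 was higher by 3.84 ± 0.88 and SHISA2 by 3.48 ± 0.61, as were GREM1, a BMP antagonist gene, by 3.03 ± 0.89, the glutathione peroxidase gene GPX3 by 2.86 ± 0.51 and IL24 by 2.72 ± 0.48. GREM1 lost its call in 9 of the 36 fits without a single array, and was not called against DMSO, with a change of 2.52 ± 0.87 (adjusted p = 0.0916). KRT19, MAL2, KRT13, SYBU and ESRP1, a splicing regulator of epithelial cells, were lower at -4.00, -3.89, -3.41, -3.36 and -3.36. Limma called 1251 genes, 763 higher and 488 lower, and 3471 without the 4 arrays. The count was 1910 and 1909 without CSC month 4 and month 3 replicate 1, and 651, 823 and 822 without CSC month 3 replicate 3, CSC month 4 replicate 2 and untreated month 2 replicate 3. The CSC arrays are shared with the comparison against DMSO, so the results are not independent. Fitted on the CSC and untreated arrays alone, the count was 688. By month, a comparison added after the data were seen, limma called 746, 0, 2 and 0 genes, with 1995, 812, 1373 and 395 at an unadjusted p under 0.05.

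Between DMSO and untreated cells, ABCA8, a lipid transporter gene, was the 1 gene called, higher by 2.23 ± 0.36 in DMSO arrays (adjusted p = 0.0358), and 387 genes had an unadjusted p under 0.05. ABCA8 averaged 8.42 ± 0.49 in DMSO and 6.64 ± 0.83 in untreated arrays in month 1. The call was lost in 23 of the 36 fits without a single array, and also with the replicate block in place of batch.

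Untreated cells at month 4 had far lower epithelial genes than at month 1. KRT19 averaged 12.70 ± 1.36 in month 1 and 3.57 ± 0.14 in month 4 (SD, n = 3 each), KRT5, a basal keratin, 10.95 ± 1.91 and 2.17 ± 0.02, and CDH1 11.04 ± 1.39 and 3.65 ± 1.07. MAL2 and S100A14 were also among the 5 largest falls of called genes. Of the 42 epithelial genes, 31 were called lower, as were 11 of 16 squamous genes. VCAN, a matrix proteoglycan gene, EDIL3, ABCC3, MYLK and AHRR were higher by 4.54, 4.18, 3.50, 3.38 and 3.35, although AHRR and VCAN lost their calls in 8 and 4 of the 36 fits without a single array. Limma called 504 genes, 157 higher and 347 lower, but 8 when the 6 arrays were fitted alone, 101 without untreated month 1 replicate 2 and 283 without untreated month 1 replicate 3. The 2 months share no batch, so month and batch cannot be told apart for this comparison, and untreated month 4 replicate 2 is 1 of the 4 arrays.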

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

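The tests of the 4 arrays, of the epithelial list by month and within batches, and of the control arrays over time were chosen after the results were seen, while the splits of the arrays were planned before their counts were known.

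The CSC minus DMSO change differed between months for 164 genes by a test of the difference itself. Adjusted p-values were 2.97e-12 for KANK4, 9.99e-10 for GJB5, 1.35e-09 for SNCAIP, 1.28e-08 for PHACTR3, 2.87e-08 for FAT2, 2.87e-08 for FGFBP1, 2.51e-07 for OVOL1 and 7.59e-07 for TTC22. These genes lay near the background outside the control arrays of months 1 and 2, so the pooled spread understates that of month 1: KANK4 had an SD of 2.07 among DMSO arrays of month 1 and 0.02 in month 4. With the mean change removed, 3 of 100 splits of the treatments within months gave as many genes as the real 164, the others giving 201 and 180. That share is under 0.05 for the fit with batch as a fixed block, and argues against chance there only weakly. The splits also treat single arrays as independent. The count was 9 with no batch term, 12 with batch as a random block and 24 with the replicate block, and no such splits were run for these fits.

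On 4 arrays CYP1B1 went against the label, and labels exchanged between arrays of a batch are a candidate explanation. A score of 405 genes, set on the arrays of months 1 and 2 and without the 4 lists of aryl hydrocarbon receptor, NRF2, epithelial and squamous genes, put 4 of the 4 arrays on the side opposite to their label and 0 of the 14 other arrays of months 3 and 4. For CSC month 4 replicate 1 this was by a margin of -0.0059 only, beside -0.0545 to -0.0347 for the month 4 control arrays on that side. The other CSC arrays of month 4 scored 0.923 and 0.811, so this array lay much closer to the controls than to them. CYP1B1 on the 2 control-labelled arrays was at least 104% of the mean of the 2 other CSC arrays of its month, the CSC array in doubt being left out, which argues against a mixture with CSC RNA in equal parts or less. Cultures that lost or gained the response were not tested, and the labels were not changed.

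The CSC minus DMSO difference of the epithelial list was smaller in later months. Exchanged labels as the whole cause are argued against by the difference of -2.9 ± 0.673 between month 1 and months 3 and 4 without the 4 arrays, and an additive batch shift by -3.35 ± 0.661 with batch as a block. The background of the arrays stays open, because DMSO arrays came down by a change of -3.25 ± 0.731 from month 1 to month 4, months that share no batch, to the level of the CSC arrays, where it can hide a difference. A loss of epithelial expression with time in culture may explain part of it, and was not tested apart from passage.

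The epithelial list was lower in control arrays at month 4. From month 3 to month 4, batch as the whole cause is argued against only weakly by the fall within the 2 shared batches, -0.839. The exact one-sided permutation p was 0.0333, the smallest that 30 assignments allow, and the side was set after the fall was seen. DMSO month 3 replicate 3 was the only month 3 control array of batch 5. Without the control array in doubt it was -0.799 (p = 0.0417 by the same exact test, the smallest that 24 assignments allow). From month 1 to month 4, untreated cells cannot be told apart from batch, because 0 batches hold untreated arrays of both months.

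A chance assignment of arrays is argued against for CSC minus DMSO over the months, where 1 of 100 splits, the real one, gave as many genes (614, highest other 141). The same holds for CSC minus untreated (1 of 100, with counts of 1251 and 419). It does not for DMSO minus untreated, where 26 of 100 splits gave at least the 1 gene called and the highest gave 280. The splits move single arrays, so they cannot exclude chance differences between cultures if the replicates of a group share a culture. Single months and the untreated cells allow 10 splits, too few for a share under 0.05. Real and highest other counts were 513 and 9 in month 1 (1 of 10 as large), 0 and 202 in month 2 (10 of 10), 0 and 610 in month 3 (10 of 10), 0 and 1 in month 4 (10 of 10), and 504 and 46 for untreated cells (1 of 10). The 610 came from the split that exchanges CSC and DMSO replicate 1 of month 3, and points to a structure of the arrays other than their labels.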

How the results depend on the processing

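Leaving out the 4 arrays, reading the values as log2 and the gene-by-gene weights, and splitting the check of replicate numbers by months, were chosen after the data were seen. Counts are in the order named, and the cause was not tested unless stated. Without the 4 arrays, 3247 genes were called for CSC minus DMSO over the months, 800, 131, 387 and 730 in months 1 to 4, 3471 for CSC minus untreated and 0 for DMSO minus untreated, with 16 lists. CDKN1C (-0.94), ABCA8 and the secretory list lost their calls (adjusted p = 0.0896, 0.429 and 0.121). The test of the fatty acid list turned from lower to higher (mean 0.373, adjusted p = 0.0327). The planned array weights did not converge and gave DMSO month 2 replicate 1 a weight of 1280, so their counts are unreliable: 3925 over the months, 2390, 971 and 3 in months 1, 2 and 4, 4615 against untreated, 2 for DMSO minus untreated, 621 for the difference between months, 1138 for untreated cells and 14 lists. Gene-by-gene weights gave 4426, 2224, 2237, 1194, 4389, 2, 716, 190 and 14. They too were highest for DMSO month 2 replicate 1, at 9.15 against 0.326 for DMSO month 2 replicate 2. These counts, that of month 2 above all, are therefore doubtful as well.

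The replicate block in place of batch gave 1111 over the months, 0 for DMSO minus untreated, 24 for the difference between months and 776 for untreated cells. Deviations from the group means were correlated between arrays of the same month and replicate number. The correlation was above 0.1 in 5 of 12 CSC and DMSO pairs, 4 of 12 CSC and untreated pairs and 7 of 12 DMSO and untreated pairs, so over the 4 months the numbers were not taken to pair the arrays. In months 1 and 2 all 6 DMSO and untreated pairs were at 0.605 to 0.879, each the best match. Of these, 5 of the 6 shared a batch, and the pair that did not, month 2 replicate 2, was at 0.857. In the same months 5 of 6 CSC and DMSO pairs and 3 of 6 CSC and untreated pairs were above 0.1. In months 3 and 4, which hold the 4 arrays, 0, 1 and 1 of 6 were, and the CSC and DMSO pair of month 3 replicate 1 was at -0.75. An array against its label moves the mean of its group, so these months cannot settle the pairing. The matches of months 1 and 2 are a hint from the data, not the design. The difference between months gave 9 genes with no batch term, 12 with batch as a random block, 85 with the stricter filter, 94 read as log2 and 328 as probe sets. Month 1 gave 242 with no batch term and 950 as probe sets. Tested as probe sets, CSC minus untreated gave 1939, DMSO minus untreated 0 and untreated cells 863. With no filter there were 375 over the months and 2 in month 4. The mean of probe sets gave 0 for DMSO minus untreated. On only the arrays compared there were 11 in month 2, 688 against untreated, 0 for DMSO minus untreated and 8 for untreated cells, with fewer degrees of freedom. At 2-fold or more there were 203 over the months and 282 against untreated, by construction. With the correlation estimated, 0 lists were called.

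Leaving out single arrays gave 295 to 1571 genes over the months, 239 to 589 in month 1, 0 to 54 in month 2, 0 to 0 in month 3, 0 to 3 in month 4, 87 to 187 for the difference between months, 651 to 1910 against untreated, 0 to 1 for DMSO minus untreated, 101 to 734 for untreated cells and 8 to 13 lists. Over the months, 1571, 1273 and 1013 genes were called without CSC month 4 replicate 1, CSC month 3 replicate 1 and DMSO month 3 replicate 1, which are 3 of the 4 arrays. Fewer were called without CSC month 2 replicate 3 (359), month 3 replicates 2 and 3 (348 and 323), and DMSO month 1 replicates 2 and 3 (295 and 395), month 2 replicate 3 (375), month 3 replicates 2 and 3 (324 and 389) and month 4 replicate 3 (312). Month 2 had 54, 6 and 1 without CSC replicate 1, DMSO replicate 1 and DMSO replicate 2, and month 4 had 3 without CSC replicate 1. Against untreated there were 1909 and 1910 without CSC month 3 and month 4 replicate 1, and 651, 823 and 822 without CSC month 3 replicate 3, CSC month 4 replicate 2 and untreated month 2 replicate 3. Without DMSO month 1 replicates 2 and 3, month 1 had 239 and 305 and the difference between months 87 and 95, and without untreated month 1 replicates 2 and 3 the untreated cells had 101 and 283. Of 72 named genes called over the months, 40 lost the call without some single array. Of 116 calls of named genes and lists over all comparisons, 33 were lost with no filter, 31 with no batch term, 31 on only the arrays compared, 22 of 106 with batch as a random block, 19 with the replicate block, 11 of 107 as probe sets, 10 of 109 with the mean of probe sets, 8 with gene-by-gene weights and 3 without the 4 arrays. The intensity trend, quantile normalization and planned weights lost at most 2 each, and the stricter filter and the log2 reading 2 of 103 and 2 of 106. Calls not recomputed are not counted as lost. GCRMA already normalizes by quantiles and the log2 reading rescales all values alike, so these settings could move little, and the planned weights are unreliable. Signal near background limits the size of falls.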

Other observations

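The test of the interferon list between months, and its use for IFIT2 and IRF1 here, were chosen after the results were seen. Among interferon response genes, 3 of 24 were lower in cells labelled CSC, MX1 by a log2 change of -1.12 ± 0.23, IFIT2 by -0.68 ± 0.14 and IRF1 by -0.54 ± 0.16 (4, adjusted over the list alone), and the list itself was not called (adjusted p = 0.141). IRF1 lost its call in 22 of the 36 fits without a single array. In month 1 IFIT2 and IRF1 were at -2.51 and -1.61, and in month 4 at 0.10 and 0.18, while MX1 was at -1.74, -1.57, -0.53 and -0.65 in months 1 to 4. The difference between months passed the test for IFIT2 (adjusted p = 0.0008) and not for IRF1 (0.196) or the list (0.0867). Among matrix protease genes TIMP3 and MMP14 were lower and TIMP4 and MMP1 higher, and MMP1 lay near the background in DMSO arrays and lost its call in 28 of the 36 fits without a single array. TIMP3 was at -6.71, -3.03, 0.46 and -0.16 in months 1 to 4, and TIMP4 at 2.12, 1.07, -0.21 and 0.14. The glutathione transferase genes GSTM3, GSTM1 and GSTM2 were higher by 0.77, 0.43 and 0.42 and the oestrogen sulfotransferase gene SULT1E1 lower at -0.95. SULT1E1 was at -3.19, -0.56, -0.03 and -0.01 in months 1 to 4 and averaged 3.16 in CSC arrays, near the background. The 3 GSTM genes are close in sequence, so which of them changed is uncertain, and GSTM2 lost its call in 26 of the 36 fits without a single array.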
